A study of Mus musculus with 15 samples.

How the data were processed

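Total RNA of mouse mammary tumours was amplified, labelled with Cy3 and hybridised to 1-colour Agilent expression arrays, per the labels' protocols. There were 15 arrays, 8 of B6 and 7 of Wsh tumours. Per the file headers, spot intensities were read with Agilent Feature Extraction 10.7.3.1, and the processed intensity is background-subtracted with spatial and multiplicative detrending and with low values replaced by a surrogate, but not normalized between arrays. The submitters' processing notes name the same program and limma. The authors also deposited a table of log2 values of the same arrays, whose background step and normalization are not given in the sources used here. In that deposited log2 table each column was in the rank order of the median spot signal minus the median background of its own array, and the column medians ranged from 8.605 to 8.608 with nearly the same distribution in every column. Its scale beyond log2, and its centring, stay unknown, and it was used as an alternative.

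Each array had 62976 spots, of which 59305 were not controls and carried 56605 distinct probes. Outlier-flagged spots were left out, spots of a probe were averaged, and 1 saturated spot on 1 array was kept. Probes were named through an accession (32994), an exact symbol (10224) or a synonym (520) in a RefSeq table of assembly GRCm38, used for names only, and 12867 kept the name in the files. Probe coordinates are those of the files (build mm9), and no exon or UTR annotation of that build was used. Probes were kept when well above background on at least 7 of 15 arrays, the size of the smaller group (34349 probes). Each gene was represented by its kept probe of highest mean over all arrays, which gave 22344 genes. The 75th percentile of the processed signal ran from 3328 to 6406 in B6 and from 3550 to 4582 in Wsh, and between 55.7% and 73.4% of non-control spots were well above background. Arrays correlated between 0.926 and 0.990 over genes, and no pair was identical.

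The main values were log2 of the processed signal minus each array's 75th percentile of it. Wsh and B6 were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05. Where no probe of a gene was well above background on any array of a group, the fold is given as a bound, against the higher of the lowest signal well above background and the probe's own signal on each array. Gene lists (33, of which 32 had at least 4 measured members) were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry. Lists, tests, the other settings below and the rule for named genes were fixed before the data were examined. The rule took Kit, Corin and every mast cell list member, the 12 largest rises and 12 largest falls among genes past the threshold that have a symbol, and up to 4 members with the largest absolute moderated t of each list called and of the hormone-sensing luminal, estrogen response, basal, proliferation, adipocyte and skeletal muscle lists. Exact permutation tests of list means between groups enumerated all splits of the 15 arrays into 8 and 7. Those of the slides enumerated all choices of slide within each group. Those of Kit used the 8 B6 arrays.

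Other settings, chosen in advance, were normexp background correction with an offset of 50 on the mean and background signals, quantile normalization, the median in place of the 75th percentile, no filter, a filter requiring all 15 arrays, the mean of a gene's probes, slide as a block and each slide alone, a replicate block, array weights, empirical Bayes with trend and robust options, adipocyte and skeletal muscle means as covariates, the deposited values, and each array left out. Settings without the 5 arrays with skeletal muscle, and with the B and plasma cell mean as a covariate, were chosen after seeing the data. The steps were tested on simulated data in which 200 of 22344 genes of this comparison were changed. Of 100 genes changed by a log2 of 2, 91% were recovered, and of 100 changed by 1, 73%. Of the 22144 genes left unchanged, 0.0226% were called. The simulated values were independent between genes, without slide effects or shared tissue content, so these shares need not hold for the real arrays. Figures were drawn with matplotlib.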

Results

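Gene expression was measured in spontaneous mammary tumours of MMTV-PyMT mice, in which the polyoma middle T oncogene is driven in mammary epithelium. The tumours came from mice on the B6 background (8 arrays) and from mice on the Wsh background (7 arrays), all at 20 weeks of age. Wsh is the usual name of mice that carry the Kit W-sh allele, an inversion of chromosome 5 beside Kit, the gene of the stem cell factor receptor, and that lack mast cells as adults. The series title names the effect of mast cells on breast cancer cells as its subject. The comparison of Wsh with B6 tumours bears on that effect but cannot isolate it. The groups also differ in the Kit allele with its inversion, and in any other DNA that differs between the backgrounds. No group separated the lack of mast cells from these, so differences below are between backgrounds and are not assigned to mast cells by the design. Each sample was 1 array of 1 tumour. The labels do not say whether any tumours shared a mouse, so p-values measure the spread between these samples. The share of non-control spots well above background was 62.3% ± 6.41 (SD, n = 8) in B6 and 63.3% ± 4.40 (SD, n = 7) in Wsh, and the number of arrays limits the precision. Values below are log2 signals relative to the 75th percentile of their array, and differences are Wsh minus B6 with the standard error (SE) of the limma fit.

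Transcripts of the mast cell chymase genes Mcpt4 and Cma1 and of Kit were lower in Wsh tumours. Mcpt4, a chymase of connective tissue mast cells, was well above background on 8 of 8 B6 arrays and on 0 of 7 Wsh arrays. Its level was at least 24.5-fold lower in Wsh (log2 difference -6.70, SE 0.78, limma adjusted p = 0.000565). That bound holds for the processed signal, since the background step set the size of such differences, and with normexp correction and in the deposited values Mcpt4 was 17.4-fold and 22.3-fold lower. Cma1, another mast cell chymase, was well above background on 7 B6 arrays and 1 Wsh array, with a log2 difference of -5.36 (SE 0.78, limma adjusted p = 0.00593) or 41.1-fold lower, against 9.32-fold with normexp correction and 11.8-fold in the deposited values. Kit was measured on all 15 arrays, with a mean of 3.24 ± 0.62 (SD, n = 8) in B6 and 0.59 ± 0.52 (SD, n = 7) in Wsh, a 6.29-fold lower level (log2 difference -2.65, SE 0.28, limma adjusted p = 0.000208). The other 2 Kit probes gave -2.40 and -2.43. The B6 and Wsh values of Mcpt4, Cma1 and Kit did not overlap. Cpa3, mast cell carboxypeptidase, was well above background on 7 B6 arrays and no Wsh array and was at least 6.48-fold lower in Wsh, with a log2 difference of -4.71 (SE 1.02) that did not pass over all genes (limma adjusted p = 0.0714). B6 replicate 3 had Cpa3 at -7.20, within the Wsh range, and without it Cpa3 passed (log2 difference -5.36, limma adjusted p = 0.0132). Leaving out any 1 of the other 14 arrays did not bring Cpa3 past the threshold, and over all settings its limma adjusted p ran from 0.00284 to 0.523.

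**Figure D1:**
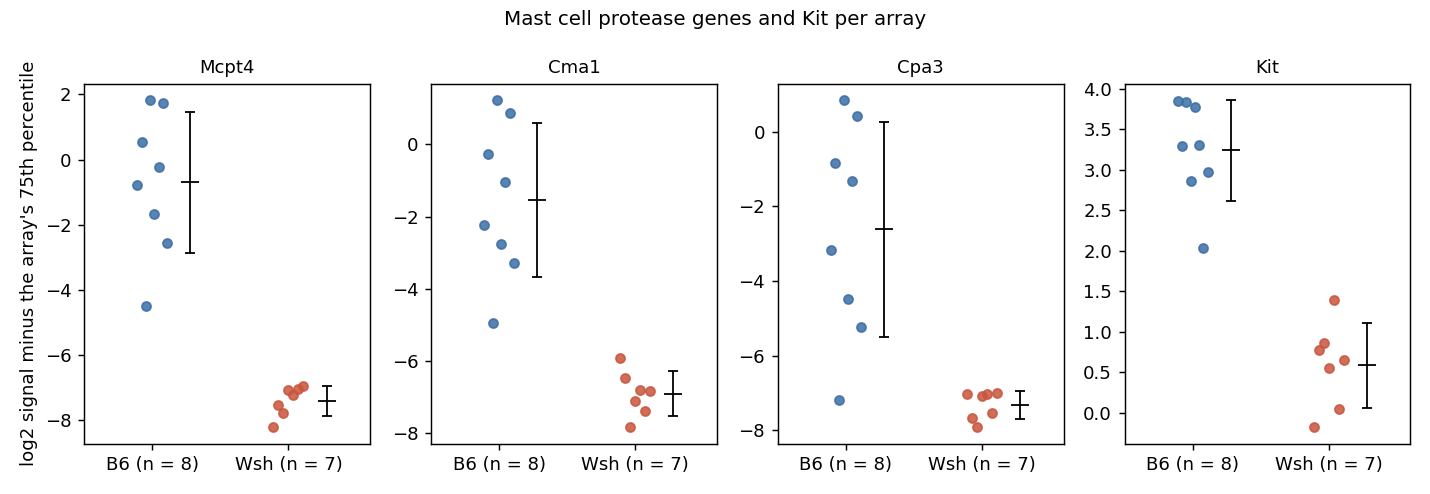
Levels of Mcpt4, Cma1, Cpa3 and Kit on each array, as log2 signal minus the 75th percentile of the array (vertical axis), in B6 and Wsh tumours; points are arrays and the bars beside them show the mean ± SD. The 7 Wsh arrays lie below the 8 B6 arrays for Mcpt4, Cma1 and Kit, and B6 replicate 3 reaches the Wsh range for Cpa3.

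Of the 19 genes in the mast cell list, 12 were measured and 3 passed over all genes, all lower in Wsh. Adjusted over the list alone, 4 passed (Kit, Mcpt4, Cma1 and Cpa3). The remaining measured members did not pass. Tpsb2, a tryptase, had a log2 difference of -0.91 (SE 0.44, limma adjusted p = 0.501). The others, with genes also used by basophils, other leukocytes or other tissues, gave -0.26 for Fcer1a, 0.38 for Hdc, 0.29 for Gata2, -0.32 for Tph1, -0.11 for Slc18a2, 0.31 for Hpgds and -0.18 for Il1rl1, with limma adjusted p between 0.707 (Hpgds) and 0.948 (Il1rl1). Hdc, Gata2, Tph1, Slc18a2 and Il1rl1 changed sign under at least 1 alternative setting. The 7 members not tested were Ctsg, Mcpt1, Mcpt2, Mrgprb1, Mrgprb2, Ms4a2 and Tpsab1. Corin, the gene at the far end of the inversion, was not well above background on any array with either of its 2 probes. The list test (camera, preset correlation 0.01) called the mast cell list lower (adjusted p = 0.000123). With an estimated correlation the adjusted p = 0.589.

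Over all genes, 75 of 22344 passed in limma, 24 higher and 51 lower in Wsh. The balance of directions depended on the setting, with 14 higher and 11 lower with no filter, 17 and 8 without the 5 arrays with skeletal muscle transcripts, and 14 and 13 without B6 replicate 6. The groups did not overlap for 51 of the 75, and for 80 of all genes (0.358%, against 0.0311% by chance). The largest rise was in Pianp (log2 difference 4.07, SE 0.39, limma adjusted p = 6.12e-05), which encodes a PILR-associating neural protein. Gm3893 was at least 2.46-fold higher, being well above background on no B6 array and on 7 Wsh arrays. 4933409K07Rik was higher by 2.81 (SE 0.37), Fam205a2 by 2.17 (SE 0.41) and Togaram2 by 1.81 (SE 0.35), from 1, 1 and 2 B6 arrays well above background. The size of these differences depended on the background step. With normexp correction Gm3893 was 2.29-fold higher, under the bound of the processed signal, and 4933409K07Rik had 1.03, Fam205a2 0.88 and Togaram2 0.77. With normexp Fam205a2 (limma adjusted p = 0.1004) and Togaram2 (0.229) no longer passed. Lrmda rose by 2.63 (SE 0.18, limma adjusted p = 1.95e-06), with 3 other probes at a median of 2.64. Atp10d, a lipid flippase gene, rose by 1.85 (SE 0.12, limma adjusted p = 1.29e-06), with its other probe at 0.53. Tlr6, a Toll-like receptor gene, rose by 1.68 (SE 0.15, limma adjusted p = 3.81e-05). Apobec1, a cytidine deaminase gene, rose by 1.36 (SE 0.20), with 2 other probes at -0.27 and 1.47. Gzmk (1.42, and 0.63 with normexp, limma adjusted p = 0.233), which encodes granzyme K of cytotoxic lymphocytes, Duxbl2 (1.18) and 5031434C07Rik (1.17) made up the 12 largest rises.

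Among genes with a symbol, the largest fall after the mast cell genes and Kit was in Uchl1, a neuronal ubiquitin hydrolase gene (log2 difference -2.33, SE 0.15, limma adjusted p = 1.29e-06, 5.02-fold lower). Gabra4, a GABA receptor subunit gene, had -1.75 (SE 0.35), with its other probe at -0.80. Tlr1, the neighbour of Tlr6, had -1.54 (SE 0.28, limma adjusted p = 0.0325), with its other probe at -1.58. Rab26, a small GTPase gene, had -1.34 (SE 0.13, limma adjusted p = 6.10e-05). Gsta2 (-1.36), a glutathione transferase gene, Kcnab3 (-1.24), Efcab12 (-1.04), Gm15327 (-1.004) and Gm4035 (-0.99) completed the 12 largest falls of genes with a symbol. TC1682181, a transcript without a symbol on chromosome 5 that was picked after its values were seen, was at least 3.08-fold lower, being well above background on 8 B6 arrays and no Wsh array (limma adjusted p = 6.12e-05), and 3.03-fold lower with normexp. Of these 24 genes, 12 passed whichever array was left out, namely Kit, Cma1, Mcpt4, Pianp, Gm3893, 4933409K07Rik, Lrmda, Atp10d, Tlr6, Apobec1, Uchl1 and Rab26. Among these 12, only Kit, Lrmda, Atp10d and Apobec1 had another kept probe. For the rest, Uchl1, Tlr6, Pianp and Rab26 among them, a sequence variant under the probe cannot be told from a change of level.

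Several of these genes lay on chromosome 5 (build mm9, by the start of the probe), with Gabra4 and Atp10d within 5 Mb of Kit and Uchl1, Tlr1 and Tlr6 farther away. The Kit probe starts at 76052394, that of Gabra4 at 71962623, that of Atp10d at 72689634 and that of Uchl1 at 67078408. The probes of Tlr1 and Tlr6 start at 65315994 and 65344365. Among the measured members of the 2 lists of genes inside and beside the inversion, 5 of 32 passed (15.6%, against 0.336% of all genes, Fisher's exact test across genes, two-sided p = 6.98e-08, genes not being independent replicates). These were Kit, Atp10d, Gabra4, Slain2 (-0.68) and Rasl11b (-0.78). The other Slain2 probe moved the opposite way (0.22), and with 1 array left out the calls of Gabra4 and Rasl11b were lost in 14 and 13 of 15 fits (highest adjusted p = 0.118 and 0.107), while Kit, Atp10d and Slain2 kept theirs. Slain2 and Rasl11b fall outside the rule for named genes and were picked after their values were seen. As lists, the genes inside the inversion (median difference 0.02, mean -0.11) and beside it (median 0.01, mean -0.07) were not called, with camera adjusted p = 0.264 and 0.377. That test asks for a shared direction, and members lay on both sides of 0 (9 higher and 9 lower inside, 7 and 7 beside). The mixed test of fry, which allows both directions, gave an unadjusted p = 1.19e-12 inside and 1.12e-13 beside. A few strong members can bring about such values, and Kit is among those beside. Adjusted over each list alone, 5 members passed inside and 5 beside.

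**Figure D2:**
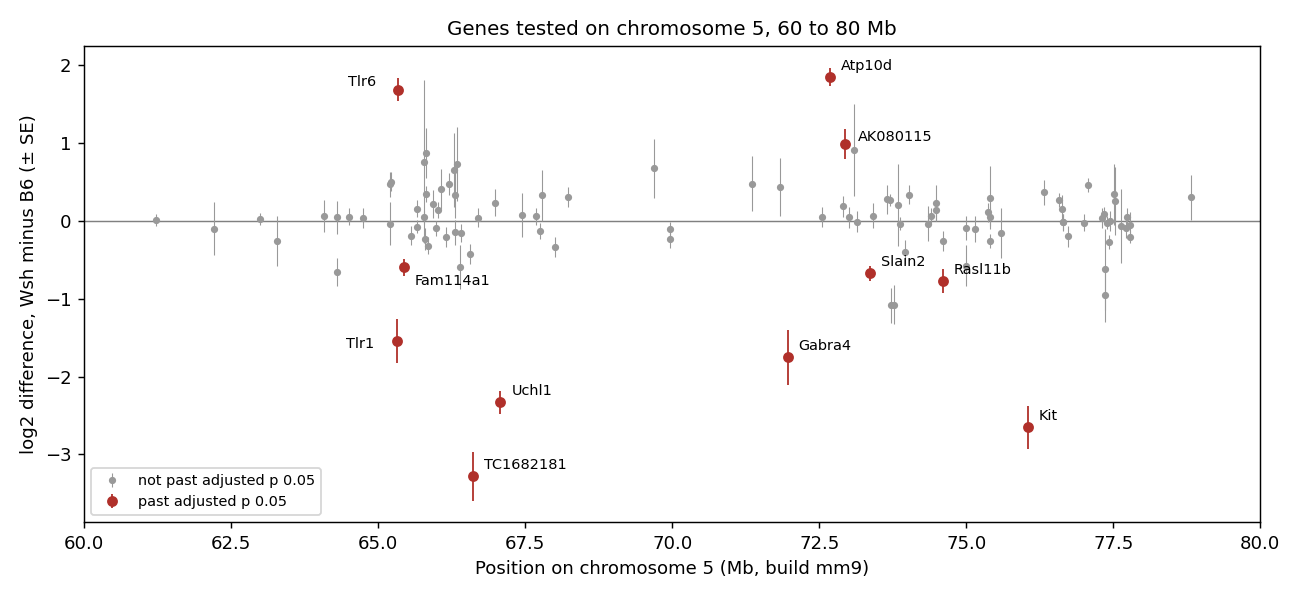
Log2 difference between Wsh and B6 tumours (vertical axis, ± SE) for the 108 genes tested between 60 and 80 Mb of chromosome 5 (horizontal axis, build mm9); red points passed adjusted p 0.05. The 11 genes that passed include both directions, with Tlr6 at 1.68 and Atp10d at 1.85 above 0 and Uchl1 at -2.33 and Kit at -2.65 below 0.

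Beyond mast cells, the list test called 6 lists of immune, inflammatory or stress genes and the skeletal muscle and adipocyte lists as higher in Wsh, and the hormone-sensing luminal list as lower, which with the mast cell list made 10 of 32. No list held with an estimated correlation (2 had an unadjusted p under 0.05 and the lowest adjusted p = 0.589). The directional test of fry called no list either (4 had an unadjusted p under 0.05 and the lowest adjusted p = 0.104). The mixed test of fry, which allows both directions, gave an unadjusted p = 1.85e-09 for the mast cell list. By exact permutation of the member means, the mast cell list passed (adjusted p = 0.0448). No other list did, cytokines and chemokines coming next (adjusted p = 0.107). The inflammatory cytokine and chemokine list had 14 of 16 members above 0 and none past the threshold over all genes (camera adjusted p = 0.000289, with an estimated correlation adjusted p = 0.589). Adjusted over the list alone, 3 passed, namely Ccl7 (1.30, SE 0.40), Ccl3 (0.82, SE 0.26) and Il1b (1.28, SE 0.42), which encode 2 chemokines and a pyrogenic cytokine. Cxcl1 had 0.86. The NK and cytotoxic list (camera adjusted p = 0.000289, with an estimated correlation adjusted p = 0.624) had 9 of 10 members above 0 and 1, Gzmk, past the threshold. Adjusted over the list alone, 3 passed, with the lymphocyte transcription factor genes Eomes (1.22, SE 0.42) and Tbx21 (0.91, SE 0.30) beside Gzmk. Ifng had 0.96.

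In the MHC class II list 9 of 9 members lay above 0, in the T cell list 14 of 15, in the macrophage list 14 of 16 and in the immediate early and heat shock list 11 of 12, and no member of these 4 passed over all genes. Their camera adjusted p were 0.00122, 0.00433, 0.00433 and 0.00433, and with an estimated correlation the adjusted p = 0.624, 0.671, 0.671 and 0.624. The T cell call was lost without Wsh replicate 1 (adjusted p = 0.147), and the macrophage call without B6 replicate 3 (0.123) or Wsh replicate 1 (0.159). With array weights the calls of T cells (0.375), macrophages (0.150) and MHC class II (0.0545) were lost, and that of macrophages also with the replicate block (0.0649) and with adipocyte and skeletal muscle covariates (0.630). Of the 10 lists called, immediate early genes (0.0695), T cells (0.0555) and hormone-sensing luminal genes (0.637) were not called on slide 1 alone, and cytokines and chemokines (0.307), macrophages (0.785), MHC class II (0.114), skeletal muscle (0.129) and adipocytes (0.517) were not called on slide 2 alone. Ciita, the class II transactivator gene, had 0.83 (SE 0.28), H2-DMb1 0.42, H2-Ab1 0.34 and H2-Aa 0.46. Of the T cell genes, Cd3e had 0.68, Cd8a 1.02, Pdcd1 0.72 and Foxp3 0.37. Cd14, the lipopolysaccharide coreceptor gene, had 0.53 (SE 0.14) and was the 1 macrophage gene to pass when adjusted over the list alone. Ms4a7 had 0.43, Mertk 0.62 and Fcgr1 0.50. The stress genes Fos, Fosb, Jun and Junb had 0.69, 0.77, 0.34 and 0.31.

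Skeletal muscle and adipocyte genes varied between arrays in the same comparison. The skeletal muscle list was called higher in Wsh (camera adjusted p = 1.85e-05, with an estimated correlation adjusted p = 0.624), with 12 of 12 members above 0 and none past the threshold. Its member mean was above the average of all arrays in Wsh replicates 1, 3, 4 and 5 and in B6 replicate 4. Myh2, a myosin heavy chain gene, had a log2 difference of 3.31 (SE 1.27), Tnni2 3.23, Tnnt3 3.49 and Mylpf 3.08. The adipocyte list was called higher (camera adjusted p = 0.0433, with an estimated correlation adjusted p = 0.733), with 13 of 14 members above 0 and none past the threshold. The adipocyte call was kept in 7 of 15 fits with 1 array left out, and was lost without B6 replicates 1 (adjusted p = 0.0871), 3 (0.499), 5 (0.0971) and 8 (0.152) and without Wsh replicates 1 (0.318), 3 (0.0659), 4 (0.0794) and 6 (0.0868). It was also lost in 11 of 18 other settings. Cidea had 0.93, Ucp1 1.38, Fabp4 0.85 and Car3 0.92. B and plasma cell genes also split the arrays, their member mean running from -2.79 to 2.14 in B6 and from -2.49 to 3.52 in Wsh. Without the 5 arrays with skeletal muscle transcripts, an alternative chosen after the data were seen, 25 genes passed in limma, 13 of them among the 75, and the lists called numbered 13, among them the mast cell list (adjusted p = 0.0138) but not skeletal muscle (0.395) or adipocyte (0.251). There Kit passed (-2.80, limma adjusted p = 0.0293), while Mcpt4 (-6.12, SE 1.08, limma adjusted p = 0.0920) and Cma1 (-4.95, SE 1.04, limma adjusted p = 0.158) did not. Over 30 other settings the adjusted p of Mcpt4 ran from 1.21e-05 to 0.326 and that of Cma1 from 0.000105 to 0.415, each past the threshold in 27.

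**Figure D3:**
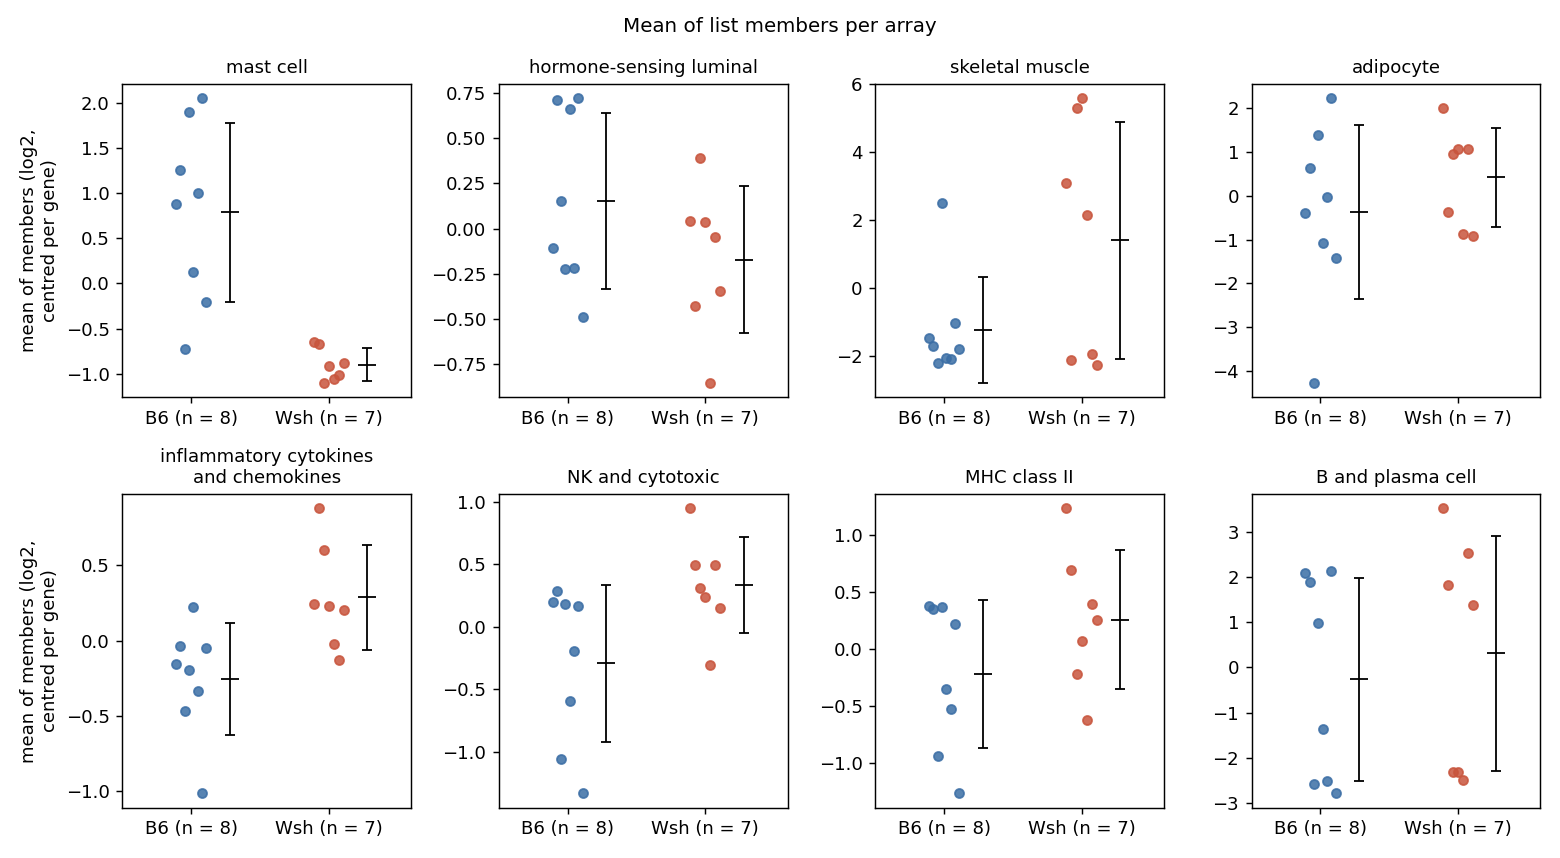
Mean of the measured members of 8 gene lists on each array (vertical axis, log2, each gene centred on its mean over all arrays), in B6 and Wsh tumours; points are arrays and the bars beside them show the mean ± SD. The skeletal muscle mean is above 0 on 4 Wsh arrays and 1 B6 array, and the B and plasma cell mean splits both groups.

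Among tumour cell lists, the hormone-sensing luminal list was called lower in Wsh (camera adjusted p = 0.0349, with an estimated correlation adjusted p = 0.624). It had 10 of 13 members below 0 and none past the threshold over all genes or over the list alone. The call was kept in 9 of 15 fits with 1 array left out, and was lost without B6 replicates 2 (adjusted p = 0.0585), 5 (0.0643) and 7 (0.142) and without Wsh replicates 2 (0.0656), 5 (0.174) and 6 (0.0616). It was also lost in 6 of 18 other settings, among them slide 1 alone (0.637), quantile normalization (0.0616), scaling by the median (0.0862) and array weights (0.334). Pgr, the progesterone receptor gene, had -0.96 (SE 0.33), Prlr, the prolactin receptor gene, -0.44 (SE 0.14), Foxa1 -0.75 and Wnt4 -0.94. The estrogen response list was not called (adjusted p = 0.377), with Siah2 at -0.23, Stc2 at -0.64 and Fkbp4 at 0.18 beside Pgr. Nor was the basal and myoepithelial list (adjusted p = 0.377), in which Lamb3, a laminin gene, had 0.89 (SE 0.22) and passed over the list alone, and Krt14 had 0.52, Trp63 0.11 and Itgb4 0.16. The proliferation list was not called (adjusted p = 0.848). Its genes Top2a, Plk1, Bub1 and Rrm2 had -0.24, 0.21, 0.16 and -0.20, and each changed sign between slides.

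The remaining lists were not called. Their camera adjusted p were 0.0555 for dendritic cells, 0.0771 for neutrophils, 0.119 for luminal epithelium, 0.213 for lymph node and lymphatic endothelium, 0.226 for Schwann cells and nerve, 0.241 for epithelial-mesenchymal transition, 0.323 for B and plasma cells and 0.383 for alveolar and milk genes. They were 0.486 for the interferon response, 0.509 for melanocytes, 0.510 for blood, 0.584 for keratinocytes, 0.651 for endothelium, 0.663 for eosinophils, 0.755 for fibroblasts and matrix, and 0.862 for both receptor tyrosine kinases with HGF and hypoxia. The median, mean and test differed in sign for the endothelial list and the receptor tyrosine kinase list (median -0.01 and -0.03, mean 0.03 and 0.04, test higher), and for both inversion lists. The basophil list had 1 measured member and was not tested.

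The arrays lay on 2 slides, each holding both groups. With slide as a block 52 genes passed, 50 of them among the 75, and within slide 1 and slide 2 alone 4 and 1 passed. All 24 genes with the largest changes kept their direction on both slides, which their choice by the difference over both slides made likely. Kit differed by -2.96 within slide 1 and -2.32 within slide 2 (-2.66 with the block). With slide as a block 9 lists were called, and within slides 8 and 7. The member mean of the mast cell list differed by -1.69 (SE 0.40) with the block, and by -1.66 and -1.73 within slides 1 and 2. These means hold Mcpt4 and Cpa3 at their measured signals, and with both at their bounds the mean difference over all arrays was -1.34. The same values, in the same order, were 0.52, 0.70 and 0.31 for cytokines and chemokines, 0.60, 0.59 and 0.60 for NK and cytotoxic genes, 0.45, 0.41 and 0.49 for MHC class II, 0.57, 0.41 and 0.76 for T cells, and 0.19, 0.35 and 0.0024 for macrophages. They were 0.33, 0.21 and 0.47 for immediate early genes, 2.48, 3.69 and 1.07 for skeletal muscle, 0.77, 1.58 and -0.17 for adipocytes, and -0.34, -0.12 and -0.59 for hormone-sensing luminal genes. Of the 32 lists, 12 had opposite signs on the slides, among them adipocytes. The alveolar and milk list had -0.15 and 1.07 and was called on slide 2 alone (camera adjusted p = 0.0219), and the B and plasma cell list had -0.42 and 1.61. The proliferation list had -0.43 and 0.53 (0.01 over all arrays) and was called lower on slide 1 (camera adjusted p = 6.38e-14) and higher on slide 2 (1.07e-15). Those p-values treat its genes as nearly independent (preset correlation 0.01), while their estimated correlation over all arrays was 0.686.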

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

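Each group of 7 or 8 arrays was screened for a single array whose gap to the nearest other array exceeded Dixon's 95% limit for its group size. Of 222 groups of values screened (named genes and list means), 24 had such an array, where chance alone gives about 1 in 20 groups, or 11.1. The covariate tests of immune lists below, and the size by which they are read, were chosen after the data were seen.

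Wsh replicate 1 accounted for 11 of the 24. It was highest among Wsh arrays for Gsta2 (-3.60), Rab26 (-1.09), H2-Aa (3.04), the endothelial list mean (0.80), the eosinophil list mean (2.003) and the macrophage list mean (0.76). It was lowest for Lamb3 (1.61), Jun (2.73), Junb (3.53), the immediate early and heat shock list mean (-0.51) and the luminal epithelium list mean (-0.58). B6 replicate 4 was the highest B6 array for Tnni2 (3.1), Mylpf (1.63), Tnnt3 (2.43) and the skeletal muscle list mean (2.52). Wsh replicate 2 was highest for Gata2 (-0.0392), the hypoxia list mean (0.65) and the keratinocyte list mean (2.21) and lowest for Tlr6 (-1.02). The other 5 were Foxa1 in B6 replicate 1 (0.81, lowest), Stc2 in B6 replicate 3 (1.76, highest), Gsta2 in B6 replicate 6 (-2.58, highest), Ccl3 in B6 replicate 7 (-3.34, lowest) and Siah2 in Wsh replicate 6 (1.56, highest).

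Because arrays of both groups differed in muscle and lymphoid transcripts, the rise of the 6 immune, inflammatory and stress lists was weighed against these tissues. The mean of their 78 measured members was 0.45 higher in Wsh, a value that carries no p because the lists were taken after they had been called higher on these arrays. With the B and plasma cell mean as a covariate the difference was 0.38 (SE 0.09), and with the skeletal muscle mean it was 0.46 (SE 0.22). Neither stayed above 0.5 of that difference by 2 SE, so the part of either tissue was not decided. A biological effect of the Wsh background stays open and untested, and so does chance, since 41 of 100 splits of the arrays gave at least as many lists as the 10 of the real split (highest other 20).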

How the results depend on the processing

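The alternatives without the 5 arrays with skeletal muscle and with the B and plasma cell mean as a covariate were chosen after the data were seen. The count of 75 genes became 25 with no filter on dim probes (37008 genes tested, 23 of them among the 75), 4 and 1 within slide 1 and slide 2 alone (fewer arrays), 15 with the replicate block, 152 with array weights (69 shared), 116 with adipocyte and skeletal muscle covariates (52 shared) and 25 without the 5 arrays with muscle (13 shared, fewer arrays). For each of these the cause was not tested. It ranged from 50 to 90 under the other settings. Scaling by the median of each array put the median difference of all genes at -0.11, against -0.01. With 1 array left out it ranged from 25 to 76, and was 38, 42, 37, 33, 25, 27 and 33 without B6 replicates 1, 2, 3, 4, 5, 6 and 8 and 31, 38, 26, 48 and 30 without Wsh replicates 2, 3, 4, 6 and 7. All 75 kept their direction with each array left out, which their choice on the same arrays made likely. When a gene's probes were averaged 2 did not, Aldh3a2 (-0.48 to 0.0147) and Man2c1os (-0.46 to 0.0465), both picked after their values were seen.

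The replicate numbers did not pair the arrays: same-numbered arrays' deviations correlated between -0.24 and 0.21, 1 of 7 pairs above 0.1, and no Wsh array correlated best with its own number. The replicate block gave 15 genes, 14 among the 75, and 9 lists.

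The 10 lists became 0 with an estimated correlation in camera and 0 with the directional test of fry (unadjusted p under 0.05 for 2 and 4 lists). They became 6 with array weights, and 7 to 13 otherwise, 7 to 12 with 1 array left out. The mast cell list passed with every array left out (highest adjusted p = 0.00214) but not with the filter on all 15 arrays (adjusted p = 0.144), which removes genes dim in Wsh.

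All 24 named genes that passed, chosen on these same arrays, kept their direction wherever tested. The filter on all 15 arrays removed 13 of them. Reversals occurred among genes that had not passed: within slide 1, Il1rl1 (0.29), Plk1 (-0.42) and Bub1 (-0.31); within slide 2, Hdc (-0.32), Gata2 (-0.11), Slc18a2 (0.0520), Cidea (-0.42), Ucp1 (-0.14), Fabp4 (-0.0046), Top2a (0.26) and Rrm2 (0.46); with array weights, Hdc (-0.0790) and Gata2 (-0.11); with tissue covariates, Ucp1 (-0.0694); without the arrays with muscle, Slc18a2 (0.15), Myh2 (-0.43) and Tnnt3 (-0.18). With 1 array left out, Il1rl1 ranged from -0.50 to 0.0417 (reversed without B6 replicates 4 and 7), Tph1 from -0.71 to 0.0708 (reversed without B6 replicate 7 and Wsh replicate 2) and Gata2 from -0.18 to 0.45 (reversed without Wsh replicate 2); the cause was not tested. Signal over background limits Mcpt4, Cma1 and Cpa3 in Wsh.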

Other observations

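The tests of chance placement of the genes called and of Kit against mast cell genes and probes were chosen after the results were seen. The mean of the proliferation list differed between backgrounds in opposite directions on the 2 slides. Singly, Top2a, Plk1, Bub1 and Rrm2 did not pass within either slide (lowest limma adjusted p = 0.373, Bub1 within slide 2). The mean of 22 proliferation genes was lower in Wsh by 0.43 within slide 1 (difference -0.43) and higher by 0.53 within slide 2. The slides differed in this (exact permutation of slide within group, two-sided p = 0.000408, the smallest the design can give, adjusted p = 0.0131 over 32 lists), and slide itself, as a grouping of the arrays, gave 11 genes and 12 lists.

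The probe used for Nnt, a mitochondrial transhydrogenase gene, was lower in Wsh (log2 difference -0.92, SE 0.16, limma adjusted p = 0.0259), but its 2 other probes gave -0.43 and 0.28, so a fall of the gene was not shown. It was picked after its values were seen, as a gene known to differ between C57BL/6 substrains.

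Kit remained high in a B6 tumour with few mast cell transcripts. Across the 8 B6 arrays Kit did not rise with the mean of Mcpt4, Cma1 and Cpa3 (Pearson r = -0.67, exact permutation p = 0.0638, Spearman rho = -0.64, exact permutation p = 0.0962, 1 relation computed, and r = -0.59 without B6 replicates 3 and 4). B6 replicate 3 had a mast cell mean of -5.54 and Kit at 3.84. The B6 line carried to the Wsh mast cell mean (-7.21) gave a Kit level of 4.21 (95% interval 2.96 to 5.46). The Wsh mean of Kit was 0.59, below that interval. The line had a negative slope (-0.17, SE 0.08), which loss of mast cells does not imply, so the size of this gap is not read. That Kit did not rise with mast cell genes in B6 argues against loss of Kit-bearing mast cells alone. The Wsh mast cell mean, however, lies beyond the B6 range. A sequence variant under 1 Kit probe is argued against by the other 2 probes, the smaller of which kept 0.904 of the fall. An effect of the Wsh background on Kit in other cells stays open and was not tested.

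Genes that passed often lay near one another: of 63 called loci (genes within 0.5 Mb merged), 30 had another within 5 Mb. The same number of top genes in 99 other splits of the arrays gave up to 31 (95% range 10 to 30). Those splits had more loci after merging (median 71), so the numbers do not have the same base. As a share of loci the 47.6% was above every other split (highest 44.3%). With number and share apart, chance placement over the genome was not decided. Of the genes in the 2 inversion lists, 5 were among those called, against 4 in the split nearest the real one (all Wsh and 1 B6 array against 7 B6 arrays) and at most 2 in the remaining 98, which argues against chance placement there. The part of adipose and muscle tissue in the tumours could not be decided for these genes. Those near another called locus kept a median of 0.984 of their difference with adipocyte and skeletal muscle covariates (95% bootstrap interval 0.948 to 1.05). Their choice made this likely, since genes that follow tissue content spread widely within groups and seldom pass. In the skeletal muscle list, whose member mean had an SD of 1.56 in B6 and 3.49 in Wsh, 0 of 12 members passed. For lymphoid tissue this share was not computed, so other tissue as a whole was not decided. For probe sequence variants, the other probes of 15 such genes gave a median of 0.459 of the difference (interval 0.207 to 0.910), 3 of them opposite in sign (Fam114a1, Slain2 and Gemin2), so this could not be decided. A biological effect of the Wsh background stays open and was not tested.

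Of 100 splits of the 15 arrays into 8 and 7, 2 gave at least the 75 genes of the real split, itself included. That share is under 0.05, which argues against chance for the gene count but does not exclude it. The other split, which mixed both groups, gave 288 genes and 16 lists. This points to a structure of the arrays that the groups do not follow. Its 7 arrays differed from the other 8 by 3.89 in the B and plasma cell mean, 1.61 in the adipocyte mean, 0.64 in the fibroblast and matrix mean and -0.75 in the skeletal muscle mean, and which of these it follows was not tested.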
